A study of Mus musculus with 18 samples.

How the data were processed

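Mature miRNAs were measured by small-RNA sequencing in 18 mouse libraries: freshly isolated ICM, ICM outgrowths after 0.5, 1, 2, 3 and 5 days, and ESC lines with 3 passage codes, each in duplicate. RNA was isolated with a PureLink miRNA kit, libraries were made with a TruSeq Small RNA kit, and sequencing was done on an Illumina GAIIx. The deposited table holds 1 score per miRNA and library, a normalized count rounded to a whole number by the authors. Their processing notes name adapter trimming with cutadapt (version not given in the sources used here), DESeq2 1.30.0 and the mm10 genome. The aligner, the counting step and the miRNA annotation are not given in the sources used here, and no label states which tool made the deposited values.

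Libraries were grouped by the description, which matches the column name, except that the day 0 columns were joined to their libraries by title. For ESC libraries the titles give other passages than the descriptions, so ESC comparisons average all 6 libraries and no passage order was used. Column names of 2 replicates per group were treated as unpaired. No library and no sample column was left out.

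Depth was read from the values. In each library the spacing of values below 1000 was searched for a step on which they fall within 0.5. A step was found in 10 libraries, with 99.2% to 100% of values on it, and the total divided by the step gave the estimated reads, 111000 to 370000. In the other 8 the step lies below the rounding, and bounds of 2320000 to 9060000 reads follow if the lowest listed value there also stands for 5 reads. A miRNA at 5 reads carries a Poisson error of 44.7% of its value, so low values are coarse. Depth and stage coincide, and each test was also made at a common floor of 27.2 normalized counts, which is 5 reads in the shallowest library.

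Tests used log2(normalized count + 1). A miRNA was tested when at least 10 in at least 2 libraries, which kept 811. Group means of the 9 groups were fitted together with limma 3.58.1 in R 4.3.3 (trend and robust options, 9 residual degrees of freedom), and adjusted p-values are Benjamini-Hochberg over the miRNAs tested in that comparison with a threshold of 0.05. Comparisons, tests, alternatives and the rule for naming miRNAs were fixed before the data were examined: ESC against ICM, outgrowths against ICM, ESC against outgrowths, each time point against the one before, ESC against day 5, any difference among ESC groups, and any difference among all groups. Fold changes are on the scale with 1 added, and where all libraries of a group are listed at 0 the change at the common floor is given instead. Elsewhere the floor value stands beside the deposited one where they lie far apart. Means are given with SD, and log2 changes with the standard error (SE) of the fit.

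Named miRNAs followed a rule. Among miRNAs at adjusted p below 0.05 with a mean of at least 100 over the 18 libraries and every library of one side above every library of the other, the 10 with the largest rise and the 10 with the largest fall were named for ESC against ICM. For outgrowths against ICM and ESC against outgrowths the number was 5 each way with group means in place of libraries, and for each time step and ESC against day 5 it was 3 each way. For the ESC groups and for all groups the 5 with the lowest p were named. Of miRNAs with identical values, 1 was named. The most abundant members of each list were also described, and any other named miRNA was chosen after its values were seen. Loci are from GENCODE vM21 on GRCm38, which placed 1355 of the 1390 miRNAs.

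The 23 lists were written from general knowledge: miR-290-295, miR-302/miR-367, miR-17-92 with paralogs, let-7/miR-98, the Sfmbt2 cluster, the Dlk1-Dio3 cluster, miR-183/miR-96/miR-182, miR-200, miR-34/miR-449, miR-15/miR-16/miR-195/miR-497/miR-322, the X-linked miR-322/miR-503/miR-351/miR-542/miR-450 cluster, miR-23/miR-27/miR-24, miR-29, miR-30, miR-26, miR-148/miR-152, miR-181, miR-125/miR-99/miR-100, and markers of fibroblasts and smooth muscle, blood, neural cells, striated muscle, and endoderm and liver. Names that differ between annotation versions (miR-292, miR-451 and miR-142) were matched after the file was seen. Lists with at least 3 tested miRNAs were tested as sets with limma camera at an inter-gene correlation of 0.01 and again with the correlation estimated from the data. Members with identical values were all kept, so list counts and camera p-values weigh such values more than once, mainly in the Sfmbt2 cluster. Counts are given as adjusted over all tested miRNAs and as adjusted over the list alone. Shares of all normalized counts were compared between 6 ESC and 10 outgrowth libraries by an exact two-sided permutation test over all splits, coded for this purpose, with Benjamini-Hochberg adjustment over lists, and again over all splits of the 8 groups with replicates kept together. Arm balance was tested with limma on the log2 ratio of the 5p to the 3p arm.

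Alternatives were pseudocounts of 0.5 and 10, no filter, a mean of at least 100, rescaling to the same total, quantile normalization, a term for replicate number, moderation without trend or robust options, array weights, leaving out each library in turn, and estimated correlation or fry for lists. Added after seeing the data were the common floor, leaving out 7 abundant miRNAs listed at 0 in some libraries, keeping 1 of each set of identical miRNAs, leaving out 669 entries numbered from 1900 and rescaling the rest, days 0 to 3 alone, leaving out P15, and contrasts between ESC groups. ESC and outgrowth labels were exchanged in 100 drawn splits of single libraries, the real one included, and, added after seeing the data, in all 56 splits of whole groups. The test was run on simulated counts with the estimated depths and the 5-read minimum. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Fastq files were not analysed here, so alignment, isomiRs and other small RNAs are not covered.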

Results

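Small RNAs were sequenced along the derivation of mouse embryonic stem cells (ESCs) from the inner cell mass (ICM), the cells of the blastocyst that give rise to the embryo proper. ICMs of the NMRI strain were isolated by immunosurgery and grown on gelatin in R2i medium with leukemia inhibitory factor. This medium combines the MEK inhibitor PD0325901 with SB431542, which blocks activin and TGF-beta type I receptors. The 18 libraries formed 9 groups of 2: ICM on day 0, outgrowths at 5 times up to day 5, and ESCs with 3 passage codes. Titles and descriptions of the ESC libraries disagree, since libraries described as P2, P4 and P15 carry passages 4, 15 and 2 in their titles. ESC groups are named here by the code in the description, and no order of passages is read from them. Values were normalized counts deposited by the authors as whole numbers for 1390 mature miRNAs, with totals of 602238 to 1265117 per library and 369 to 928 miRNAs above 0.

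miR-92a-3p, of the miR-17-92 clusters that support proliferation, was the most abundant miRNA in each library of days 0 to 5, with 12.8% to 24.9% of all normalized counts. Among ESC libraries the most abundant was miR-191-5p in P15 (21.7% and 22.1%), miR-182-5p in P2 (14.6% and 14.9%), and miR-541-5p (14.1%) or miR-92a-3p (13.1%) in P4. Replicates correlated at a Pearson r of 0.86 for ICM and up to 0.977 elsewhere. No pair matched within sampling noise, with chi-square per miRNA between 1.74 and 18.8 where 1 would be sampling alone. Nothing in the labels says that replicates came from separate embryos or cultures. The limma p-values measure the spread between replicates of a group. In comparisons that average groups, differences among ESC groups or among outgrowth days do not enter that spread.

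Sequencing depth moved with stage. In the 10 libraries of days 0 to 3 the low values were evenly spaced, 1 read being worth 1.73 to 5.44 normalized counts, and the lowest listed value equalled 5 reads. These libraries held an estimated 111000 to 370000 reads. In the 8 libraries of day 5 and ESCs the spacing lay below the rounding, and with the same 5-read minimum they would hold 2320000 to 9060000 reads, 6.3 to 81.6 times as many. A miRNA with fewer than 5 reads is listed at 0, so 0 can stand for any value below 27.2 normalized counts in the shallowest library. Each comparison was therefore repeated at a common floor, chosen after seeing the data, in which values below 27.2 were raised to 27.2. Replicates raised to the floor become identical, so the spread between them is set and not measured. For miRNAs with many such values, p-values at the floor may be too low. In simulated counts with this depth difference, the test on values as deposited called 76 of 461 unchanged miRNAs (16.5%) in ESCs against ICM, 75 of them as higher. The floor brought this to 2 of 344 (0.6%) and recovered 67.9% of changes of 1 log2 and 81.2% of changes of 2 log2.

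To find the miRNAs that separate the end of derivation from its start, the 6 ESC libraries were compared with the 2 ICM libraries. miR-363-3p and miR-106a-5p, encoded together on the X chromosome in a paralog of the proliferation-linked miR-17-92 cluster, were listed at 0 in both ICM libraries. In ESCs they reached 892.5 ± 479.9 and 458 ± 241 normalized counts (SD, n = 6), with log2 changes at the common floor of 4.88 (limma adjusted p = 2.86e-10) and 3.92 (adjusted p = 2.64e-09). miR-335-3p, from an intron of the imprinted gene Mest, went from 0 to 684 ± 216 (4.60 at the floor, limma adjusted p = 8.66e-09). miR-5119, an entry within an intron of Cdk12, fell from 891.5 ± 484.4 to 1 ± 1.67 (log2 change -9.04, SE 0.65, limma adjusted p = 4.72e-07; -4.92 at the floor).

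Other miRNAs listed at 0 in both ICM libraries came from several loci. From the imprinted Dlk1-Dio3 region, expressed from the maternal chromosome 12, miR-382-5p reached 686 ± 559.9 (3.94 at the floor, limma adjusted p = 3.01e-07) and miR-369-5p 272 ± 191 (2.64, adjusted p = 5.31e-08). miR-434-5p of the same region was listed at 0 in 1 ICM library and rose from 31.0 ± 43.8 to 1649 ± 1117 (log2 change 7.08, SE 1.05, limma adjusted p = 1.44e-04; 4.71 at the floor). Both arms of miR-708, which lies in Tenm4, appeared: miR-708-5p at 353 ± 135 (3.59 at the floor, limma adjusted p = 2.39e-07) and miR-708-3p at 279.8 ± 94.0 (3.30, adjusted p = 9.16e-07). miR-34c-5p, a p53 target, reached 284 ± 153 (3.21 at the floor, limma adjusted p = 1.07e-06) and the X-linked miR-542-3p 169 ± 103 (2.35, adjusted p = 6.61e-06).

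Among the miRNAs lower in ESCs, miR-5108 was listed at 0 in all 6 ESC libraries against 487.5 ± 12.0 in ICM (-4.16 at the floor, limma adjusted p = 1.08e-07). miR-5130, in an exon of Kctd12, fell from 17676 ± 7649.5 to 222 ± 134 (log2 change -6.43, SE 0.43, limma adjusted p = 2.39e-07). miR-877-3p, a mirtron of Abcf1 that is spliced rather than cut by Drosha, fell from 963 ± 354 to 23.5 ± 15.8 (-5.60, SE 0.25, limma adjusted p = 7.20e-09, and -4.90 at the floor). let-7d-3p fell from 305 ± 46.7 to 2.5 ± 2.43 (-6.75, SE 0.41, limma adjusted p = 7.65e-08, and -3.48 at the floor). Falls were also called for miR-6982-3p (-8.41, SE 0.96, limma adjusted p = 1.78e-05), miR-7211-5p (-7.83, SE 1.45, adjusted p = 7.15e-04), miR-1934-5p (-7.29, SE 0.56, adjusted p = 7.89e-07) and miR-7000-5p (-6.51, SE 1.15, adjusted p = 5.21e-04). At the floor these falls were -3.80, -4.22, -5.69 and -5.72. miR-2861 fell from 1952 ± 1299.7 to 22.2 ± 22.2 (-6.84, SE 2.18, limma adjusted p = 0.0198, and -5.78 at the floor), a call lost without either ICM library (adjusted p = 0.102 and 0.0525). Entries numbered from 1900, as most of these are, held 18.7 ± 0.21% of all normalized counts in ICM and 2.38% to 4.73% in the ESC groups.

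Of 811 miRNAs tested, 256 rose and 192 fell in ESCs against ICM (Benjamini-Hochberg adjusted p below 0.05). At the common floor 195 of the 256 rises (76.2%) and 161 of the 192 falls (83.9%) were still called. Array weights, which trust libraries unequally, gave 250 calls in place of 448, and miR-2861 and miR-7000-5p lost theirs (adjusted p = 0.26 and 0.179). With libraries rescaled to the same total, the median change of all tested miRNAs moved from 0.01 to -0.48. ESC libraries have higher totals (781162 to 1265117) than ICM libraries (602238 and 625749). Rescaling therefore lowers the list medians of this comparison as well, and the rescaled value is given below for some lists only.

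**Figure D1:**
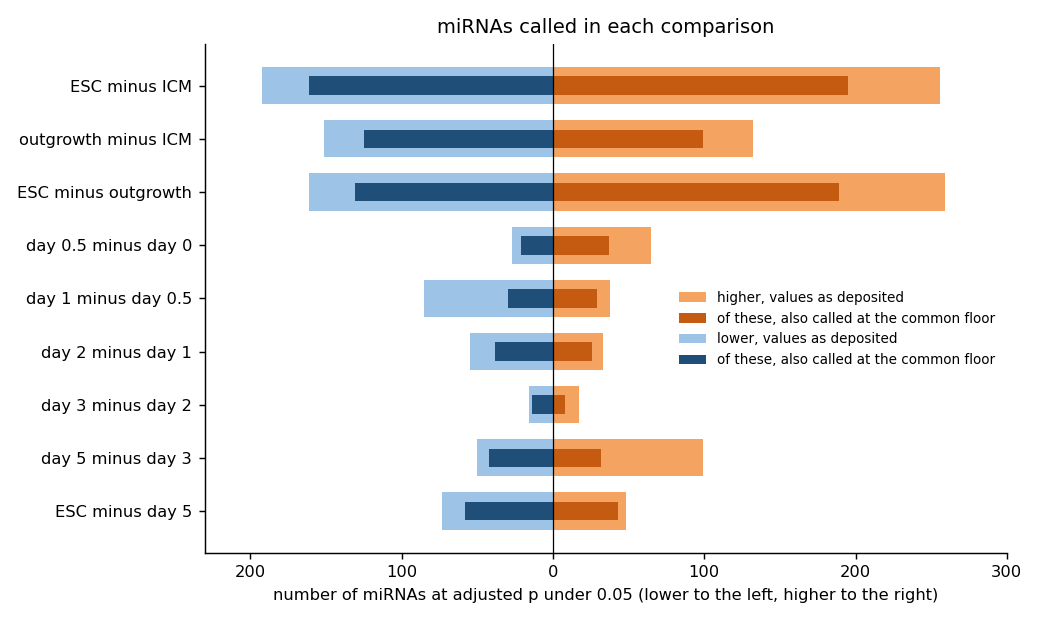
miRNAs called in each comparison, lower to the left and higher to the right, on the values as deposited (pale bars) and the part also called with all libraries held to the common floor (dark bars).

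Families and clusters with known roles in pluripotency or proliferation were followed as lists in the same comparison; counts adjusted over the list alone were the same unless given. Of 84 tested miRNAs of the Dlk1-Dio3 cluster, 64 rose and 4 fell in ESCs (68 and 4 adjusted over the list alone; median log2 change 3.55, or 1.71 at the common floor and 4.64 without P15; camera adjusted p = 8.53e-12, adjusted p = 0.0226 with an estimated correlation). miR-541-5p, its most abundant member, went from 3771 to 64211 in P2, 133700 in P4 and 9704 in P15 (log2 change over all ESCs 3.51, SE 0.28, limma adjusted p = 1.12e-06). In the miR-17-92 and paralogous clusters 20 of 24 rose and 1 fell (21 and 1 adjusted over the list alone; median 2.91, or 1.71 at the floor; camera adjusted p = 1.85e-04, and 0.0691 with an estimated correlation). miR-93-5p of these clusters rose by 1.93 (SE 0.14, limma adjusted p = 3.76e-07), whereas the change of miR-92a-3p, 0.21, turned to -0.51 with libraries rescaled to the same total. Of the miR-302/miR-367 cluster, which marks the post-implantation epiblast, 7 of 8 rose and 0 fell (median 4.51, camera adjusted p = 0.00295; adjusted p = 0.0563 with an estimated correlation), and miR-302d-3p rose by 6.0 (SE 1.17, limma adjusted p = 0.00102; 3.63 at the floor). At the common floor the median of this cluster was 1.05 with an adjusted p of 0.051. The other lists were not called as sets in this comparison.

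The miR-290-295 cluster, known for its role in the ESC cell cycle, had 4 of 14 members higher and 2 lower in ESCs, and its median change of 0.14 was -0.58 with libraries rescaled to the same total. let-7/miR-98, which promote differentiation and are held back by Lin28 in ESCs, had 1 higher and 6 lower of 11 (median -1.08, camera adjusted p = 0.197). let-7f-5p fell by 2.13 (SE 0.13, limma adjusted p = 7.65e-08) and let-7e-5p by 2.97 (SE 0.15, adjusted p = 1.26e-08). In the rodent-specific Sfmbt2 cluster 23 of 52 rose and 13 fell, and the median of 0.56 was 0.15 at the floor and -0.07 with libraries rescaled to the same total. miR-466b-3p fell by 2.77 (SE 0.12, limma adjusted p = 7.20e-09) and miR-669a-5p rose by 1.4 (SE 0.15, adjusted p = 9.30e-06). The miR-183/miR-96/miR-182 cluster, known from sensory and epithelial cells, had 5 of 6 higher and 1 lower (median 2.92, or 2.68 at the floor), with miR-183-5p rising by 4.46 (SE 0.52, limma adjusted p = 1.99e-05). In the miR-15/miR-16/miR-195/miR-497/miR-322 family, which slows the cell cycle, 5 of 9 rose and 0 fell (median 1.21), led by miR-16-5p with 2.76 (SE 0.13, limma adjusted p = 1.22e-08). The X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450 had 5 of 11 higher and 1 lower (6 and 1 adjusted over the list alone; median 1.21, or 0.32 at the floor), and miR-351-5p was the one lower (-2.79, SE 0.24, limma adjusted p = 1.59e-06).

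Among widely expressed families, 6 of 6 miR-181 members rose and 0 fell (median 3.5, or 1.69 at the common floor), with miR-181c-5p rising by 2.97 (SE 0.42, limma adjusted p = 9.13e-05). The miR-23/miR-27/miR-24 clusters had 4 of 8 higher and 0 lower (median 1.28, or 0.49 at the floor), and miR-27b-3p rose by 3.16 (SE 0.22, limma adjusted p = 3.66e-07). For miR-34/miR-449 the counts were 3 of 4 higher and 0 lower (median 3.85). At the floor the median was 2.76, from miR-34c-5p (3.21) and miR-34a-5p (2.3) alone. In miR-148/miR-152, which represses Dnmt1, 3 of 6 rose and 0 fell (3 and 1 adjusted over the list alone, with a median of 1.69, or 0.26 at the floor). The 1 lower was miR-148b-3p (-3.83, or -1.44 at the floor), which is listed at 0 in both P2 libraries and P4 replicate 1. The other ESC libraries held miR-148b-3p at 439 to 745, above the 348 and 360 of ICM. miR-30 had 4 of 11 higher and 2 lower (median -0.35), and miR-200, which marks epithelia, 2 of 8 higher and 0 lower, with a median of 0.42 that was 0.07 at the floor and -0.28 with libraries rescaled to the same total. In miR-26, 1 of 3 rose and 0 fell, the median being -0.37 as deposited, 1.23 at the floor and 0.63 after quantile normalization. miR-26a-5p was its riser (2.82, SE 0.16, limma adjusted p = 7.65e-08). The median of -0.37 is that of miR-26b-5p, listed at 0 in both P4 libraries. P2 and P15 held miR-26b-5p at 1057 to 1562, above the 207 and 115 of ICM. miR-125/miR-99/miR-100 had 0 of 8 higher and 3 lower (0 and 2 adjusted over the list alone; median -0.21). Of miR-29, which represses DNA methyltransferases, 1 member was tested: miR-29a-3p, listed at 0 in both ICM libraries, reached 126.5 in P2, 81.0 in P4 and 105 in P15 (1.91 at the floor, limma adjusted p = 2.45e-07).

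Markers of other cell types were followed in the same way. Fibroblast and smooth muscle markers had 4 of 10 higher and 4 lower (4 and 6 adjusted over the list alone; median -1.39, or -0.57 at the floor), with miR-10b-5p falling by 2.97 (SE 0.38, limma adjusted p = 4.54e-05). Blood cell markers had 3 of 5 higher and 1 lower (median 2.28, or 1.29 at the floor): miR-142-5p rose by 2.32 (SE 0.29, limma adjusted p = 3.38e-05) and miR-486-5p fell by 3.67 (SE 0.37, adjusted p = 6.24e-06). Neural markers had 4 of 12 higher and 1 lower, with a median of 0.96 that was -0.13 at the common floor. Striated muscle markers had 1 of 3 higher and 0 lower, with a median of 1.37. At the floor only miR-133a-3p (-0.33) and miR-499-5p (0.24) were tested, with a median of -0.05. Endoderm and liver markers had 1 of 4 higher and 0 lower, the median of 0.27 becoming -0.03 at the floor and -0.10 with libraries rescaled to the same total; miR-375-3p rose by 2.74 (SE 0.46, limma adjusted p = 3.37e-04).

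Outgrowths of days 0.5 to 5 were next compared with ICM, to see what changes once the cells are in culture. miR-335-3p of the imprinted Mest locus and miR-450b-5p of an X-linked cluster induced on differentiation were listed at 0 in both ICM libraries. Over the 10 outgrowth libraries they averaged 248 ± 159 and 148.6 ± 78.0 normalized counts (SD), with 2.86 (limma adjusted p = 9.12e-07) and 2.24 (adjusted p = 6.98e-06) log2 at the common floor. miR-363-3p reached 358 ± 423 (2.48 at the floor, limma adjusted p = 6.48e-08), rising with each time point from 8.5 on day 0.5 to 1085 on day 5, and miR-467b-5p reached 132.7 ± 131.0 (1.78, adjusted p = 1.71e-04). miR-92b-3p rose from 2325.5 ± 3288.8 to 23955 ± 8617 (log2 change 8.37, SE 2.04, limma adjusted p = 0.00807; 5.99 at the floor), but was listed at 0 in 1 ICM library and in both P2 libraries while other libraries held 4651 to 36603.

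Among the miRNAs lower in outgrowths, miR-6236 was listed at 0 in 9 of 10 outgrowth libraries against 704.5 ± 526.8 in ICM (log2 change -8.61, SE 1.13, limma adjusted p = 1.36e-04; -4.32 at the common floor). miR-3473e fell from 1662.5 ± 71.4 to 144.5 ± 226.4 (-6.31, SE 1.46, limma adjusted p = 0.00596) and miR-714 from 726.5 ± 202.9 to 110.1 ± 135.2 (-4.08, SE 0.94, adjusted p = 0.00584). miR-7211-5p (-4.73, SE 1.38, limma adjusted p = 0.0205) and miR-709 (-4.62, SE 1.37, adjusted p = 0.0229) also fell. At the floor the changes were -4.41 for miR-3473e, -3.45 for miR-714, -3.29 for miR-7211-5p and -3.13 for miR-709. The last 2 calls were lost without either ICM library, at adjusted p of 0.08 and 0.0875 for miR-7211-5p and 0.0624 and 0.125 for miR-709.

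By list, 39 of 84 Dlk1-Dio3 miRNAs rose and 1 fell in outgrowths (42 and 2 adjusted over the list alone; median 1.85, or 0.75 at the common floor; camera adjusted p = 9.23e-13, adjusted p = 0.0171 with an estimated correlation). Of miR-302/miR-367, 5 of 8 rose and 0 fell (median 3.07, or 0.93 at the floor; camera adjusted p = 0.00353, adjusted p = 0.0511 with an estimated correlation). The miR-17-92 clusters had 14 of 24 higher and 1 lower (17 and 1 adjusted over the list alone; median 1.48, or 0.62 at the floor; camera adjusted p = 0.00409, adjusted p = 0.15 with an estimated correlation). In the X-linked miR-322/miR-503 cluster 5 of 11 rose and 1 fell (median 1.56, or 1.82 at the floor; camera adjusted p = 0.0258, adjusted p = 0.115 with an estimated correlation), with miR-322-5p up by 1.85 (SE 0.14, limma adjusted p = 2.51e-06). Of miR-290-295, 0 of 14 were higher and 5 lower, and the set was not called (median -0.62, camera adjusted p = 0.108).

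Over all miRNAs, 132 rose and 151 fell in outgrowths against ICM (limma, Benjamini-Hochberg adjusted p below 0.05), and 99 and 125 of these were still called at the common floor. Array weights gave 61 calls in place of 283, 39 higher and 22 lower, and ended the calls of miR-3473e, miR-714, miR-7211-5p and miR-709 (adjusted p = 0.188, 0.271, 0.358 and 0.394). The median change of all tested miRNAs, -0.31 as deposited, was -0.52 with libraries rescaled to the same total and -0.03 after quantile normalization.

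ESCs were then compared with outgrowths to find what is gained or lost as outgrowths become lines. miR-210-3p, induced by hypoxia, rose from 71.3 ± 59.6 to 929.8 ± 541.0 (log2 change 4.15, SE 0.99, limma adjusted p = 0.00453), and miR-196a-5p, encoded in Hox clusters, from 35.8 ± 20.7 to 356 ± 206 (3.52, SE 0.86, adjusted p = 0.00544); at the common floor these rises were 3.63 and 3.02. miR-708-5p rose from 53.8 ± 63.6 to 353 ± 135 (3.92, SE 0.70, limma adjusted p = 6.18e-04) and miR-34c-5p from 48.3 ± 42.0 to 284 ± 153 (3.78, SE 0.62, adjusted p = 3.57e-04), or 2.82 and 2.36 at the floor. miR-25-3p, encoded in Mcm7 with miR-93 and miR-106b, rose from 1634 ± 941 to 9711 ± 2958 (4.41, SE 0.11, limma adjusted p = 1.57e-10; 3.46 at the floor). This average includes day 5, where both libraries list miR-25-3p at 0 while all others hold 1716 to 14185.

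miR-5108, listed at 0 in all ESC libraries, averaged 189.5 ± 174.7 in outgrowths (-2.09 at the common floor, limma adjusted p = 7.99e-07). let-7d-3p fell from 172 ± 108 to 2.5 ± 2.43 (log2 change -5.51, SE 0.26, limma adjusted p = 8.69e-09) and miR-5119 from 258 ± 308 to 1 ± 1.67 (-6.57, SE 0.41, adjusted p = 1.49e-07), or -2.24 and -2.44 at the floor. miR-6982-3p fell by 5.06 (SE 0.61, limma adjusted p = 3.33e-05), or 1.49 at the floor. miR-92b-3p fell from 23955 ± 8617 to 9459 ± 7904 (-5.30, SE 1.36, limma adjusted p = 0.00696, and -3.71 at the floor), a value that includes its 0 in both P2 libraries.

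The let-7/miR-98 family, opposed by Lin28 in pluripotent cells, had 1 higher and 6 lower of 11 in ESCs against outgrowths (median -1.06, camera adjusted p = 0.0156; adjusted p = 0.237 with an estimated correlation). In the Dlk1-Dio3 cluster 50 of 84 rose and 6 fell (53 and 6 adjusted over the list alone; median 1.52, or 0.74 at the common floor; camera adjusted p = 1.42e-05, adjusted p = 0.174 with an estimated correlation). This value mixes ESC groups that run opposite ways: without P15, 65 rose and 2 fell, with a median of 2.67. miR-17-92 clusters had 17 of 24 higher and 2 lower (18 and 2 adjusted over the list alone; median 1.63, or 1.1 at the floor; camera adjusted p = 0.00403, adjusted p = 0.174 with an estimated correlation). For miR-302/miR-367, 6 of 8 rose and 0 fell (median 1.77, camera adjusted p = 0.04; adjusted p = 0.174 with an estimated correlation), and at the common floor the median was 0.20 and the adjusted p 0.214. ESC groups differed here as well, since its share was 0.48% in P2 but 0.02% in P4 and 0.07% in P15, against 0.1% on day 3 and 0.25% on day 5. miR-16-5p rose by 1.75 (SE 0.08, limma adjusted p = 1.18e-08) and miR-351-5p fell by 3.09 (SE 0.15, adjusted p = 1.46e-08).

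In total 259 miRNAs rose and 161 fell (limma, Benjamini-Hochberg adjusted p below 0.05), and 189 and 131 were kept at the common floor. Without entries numbered from 1900 the calls numbered 269. With libraries rescaled to the same total the calls were 191 higher and 183 lower, and the median of all miRNAs moved from 0.28 to -0.13. Labels exchanged among the 16 single libraries, which separates replicates, gave at most 86 calls against 420 for the real split, and 140 against 378 at the common floor. In splits that keep replicates together, added after seeing the data, days 0.5, 1 and 2 against the other groups gave 445, and 387 at the floor.

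Shares of all normalized counts were compared between the 6 ESC and 10 outgrowth libraries for each list with an exact permutation test over single libraries. This test counts replicates of a group as independent, so its p-values are lower than the 8 groups allow. Over the 56 splits of whole groups, added after seeing the data, no list was called (lowest adjusted p = 0.183), and 4 lists reached the lowest p possible, 0.0357. These were miR-17-92, miR-34/miR-449, the X-linked miR-322/miR-503 cluster and miR-23/miR-27/miR-24. In the test over libraries, the miR-23/miR-27/miR-24 clusters took 1.28 ± 0.24% in ESCs and 0.48 ± 0.13% in outgrowths, and the X-linked miR-322/miR-503 cluster 0.33 ± 0.09% and 2.85 ± 1.42% (both adjusted p = 0.00287 in the exact test). The cell cycle family of miR-15 and miR-16 took 2.57 ± 0.84% and 1.24 ± 0.41% (exact adjusted p = 0.0103). miR-183/miR-96/miR-182 took 17.3 ± 5.44% and 10.6 ± 4.42% (exact adjusted p = 0.0341), with 3.62% in ICM, 15.3% on day 3, 11% on day 5, 16.7% in P2, 11.6% in P4 and 23.5% in P15. The miR-17-92 clusters took 13.1 ± 1.43% in ESCs and 18.5 ± 4.07% in outgrowths (exact adjusted p = 0.0124). Most of this share was miR-92a-3p (24.9% of 26.6% in day 5 replicate 1), whereas more members of the list rose than fell in ESCs. In outgrowths the X-linked share was likewise mostly miR-351-5p, at 33718 normalized counts in day 2 replicate 1 against 1031 for miR-322-5p. Neither share stands for all members of its list. let-7/miR-98 took 0.21 ± 0.1% and 0.59 ± 0.34% (exact adjusted p = 0.0172) and fibroblast and smooth muscle markers 2.26 ± 0.71% and 4.01 ± 0.8% (exact adjusted p = 0.0101). The fibroblast share, too, was mostly 2 members, miR-22-3p and miR-10b-5p, at 19488 and 21292 normalized counts in day 3 replicate 1. miR-22-3p held 13489 to 19488 in outgrowths. Its values were 21556 and 22445 in P4, 16774 and 16505 in P2, and 10944 and 10712 in P15. This share does not stand for its list either. The miR-290-295 cluster held 16.7 ± 1.47% in ICM, 10.5 ± 2.4% in outgrowths and 12.2 ± 2.1% in ESCs (exact adjusted p = 0.235). The Dlk1-Dio3 share climbed from 2.06 ± 0.07% in ICM to 11.6% on day 5. In the ESC groups it was 20.7 ± 0.62% in P2, 26.2 ± 0.15% in P4 and 1.79 ± 0.07% in P15 (ESCs against outgrowths, exact adjusted p = 0.0712). Of the 23 lists, 14 were called over single libraries and 0 over whole groups. With 0.0357 as the lowest p possible, a call over whole groups would need most of the 23 lists at that p. The 0 was therefore nearly fixed by the number of splits.

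**Figure D2:**
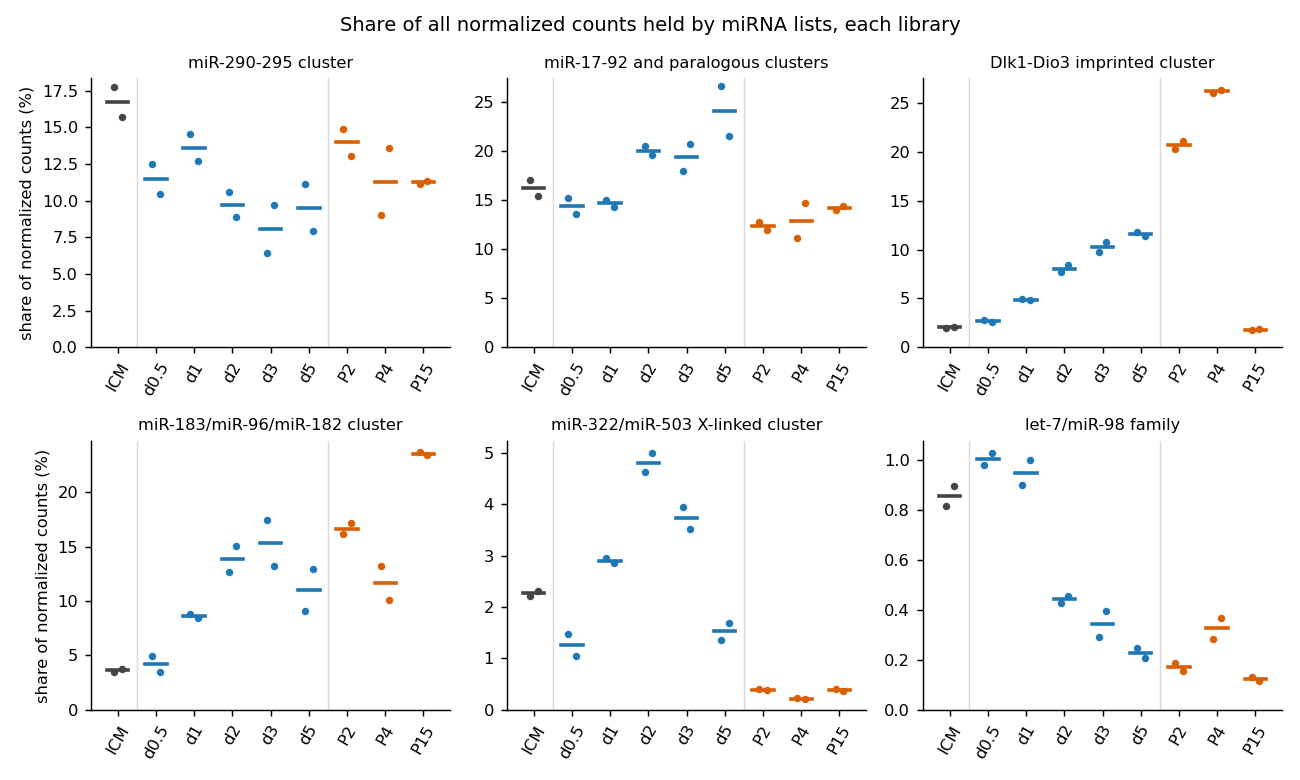
Percent of all normalized counts held by 6 lists in each library (points) with group means (bars); ICM gray, outgrowths blue, ESCs orange.

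Successive time points were compared to place these changes, starting with day 0.5 against day 0. miR-335-3p, of imprinted Mest, was listed at 0 in both ICM libraries and reached 77 ± 4.24 within 0.5 days (SD, n = 2; 1.5 at the common floor, limma adjusted p = 0.00238). miR-486-5p, abundant in red blood cells and listed with the same values as miR-3107-5p, fell from 2288 ± 382 to 226 ± 14.1 (log2 change -3.33, SE 0.45, limma adjusted p = 3.64e-04). miR-26a-5p rose by 1.22 (SE 0.20, limma adjusted p = 0.00162) and miR-409-3p of the Dlk1-Dio3 cluster by 0.88 (SE 0.09, adjusted p = 4.74e-05). miR-467b-5p and miR-450b-5p went from 0 to 55.5 ± 29.0 and 47.5 ± 2.12, which the common floor does not separate (adjusted p = 0.0839 and 0.0688).

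miR-6236 fell from 704.5 ± 526.8 to 36.5 ± 51.6 (log2 change -6.12, or -3.75 at the floor; SE 1.46, limma adjusted p = 0.0173, and 0.0843 without ICM replicate 1). miR-150-5p, of lymphocytes, fell from 73.0 ± 11.3 to 27 ± 8.49 (-1.43, SE 0.36, adjusted p = 0.0255; 0.0773 without ICM replicate 2 and 0.181 without day 0.5 replicate 2). Between day 0 and day 0.5, 65 miRNAs rose and 27 fell (limma, Benjamini-Hochberg adjusted p below 0.05), with 37 and 21 kept at the common floor. The number called was 168 in place of 92 without ICM replicate 2, 20 with array weights, 39 without entries numbered from 1900 and 58 in days 0 to 3 alone. Array weights ended the calls of miR-6236, miR-486-5p and miR-150-5p (adjusted p = 0.163, 0.237 and 0.877), and days 0 to 3 alone those of miR-6236 and miR-150-5p (0.133 and 0.103). miR-150-5p was also lost with libraries rescaled to the same total (0.0582), without trend and robust options (0.0531) and without entries numbered from 1900 (0.0906). Entries numbered from 1900 held 27.6 ± 5.57% of counts on day 0.5, against 18.7 ± 0.21% on day 0.

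From day 0.5 to day 1 the imprinted Dlk1-Dio3 cluster had 14 of 84 members higher and 0 lower, after 10 and 0 in the step before (14 and 1 adjusted over the list alone; median 0.45, or 0.24 at the common floor; camera adjusted p = 4.62e-09, adjusted p = 0.0545 with an estimated correlation). miR-409-3p rose by 0.80 (SE 0.09, limma adjusted p = 1.21e-04). The proliferation-linked miR-17-92 clusters had 3 of 24 higher and 0 lower (median 0.41, camera adjusted p = 0.0364; adjusted p = 0.382 with an estimated correlation and 0.0783 at the floor). miR-182-5p rose by 1.08 (SE 0.28, limma adjusted p = 0.0250) and miR-222-3p from 9.5 ± 13.4 to 82.5 ± 17.7 (4.21, or 1.58 at the floor; SE 1.00, adjusted p = 0.0163). miR-302b-3p, listed at 0 up to day 0.5, was at 28 ± 11.3 on day 1 and miR-6944-3p went from 4.5 to 39.5, steps that the common floor does not separate (adjusted p = 0.795 and 0.606). miR-212-5p, a CREB-induced neuronal miRNA, fell from 850.5 ± 252.4 to 16 ± 22.6 (-7.18, SE 1.57, limma adjusted p = 0.0108). miR-346-5p fell from 666.5 ± 518.3 to 8.0 ± 11.3 (-7.08, SE 1.49, adjusted p = 0.00867) and miR-3473a from 295 ± 42.4 to 27 ± 38.2 (-5.31, SE 1.35, adjusted p = 0.0224). At the floor these falls were -4.82, -4.36 and -2.94.

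Calls numbered 38 higher and 85 lower for day 1 against day 0.5 (limma, Benjamini-Hochberg adjusted p below 0.05), of which 29 and 30 were kept at the common floor. After quantile normalization they were 64 and 71, the median of all miRNAs moving from -0.22 to 0.18. The total of 123 was 66 without day 0.5 replicate 2, 63 without day 1 replicate 1, 57 with array weights or in days 0 to 3 alone, and 36 without entries numbered from 1900. Those same libraries carried the calls of miR-212-5p (adjusted p = 0.0612 and 0.0864), miR-346-5p (0.0672 and 0.079) and miR-6944-3p (0.0852 and 0.116). miR-3473a was lost without either day 0.5 library (0.0644 and 0.0958) and miR-222-3p without either day 1 library (0.0657 and 0.0646). Array weights ended the calls of miR-6944-3p, miR-212-5p, miR-346-5p and miR-3473a (0.0727, 0.14, 0.0818 and 0.114). Days 0 to 3 alone ended the same 4 (0.165, 0.0659, 0.0777 and 0.108) and that of miR-222-3p (0.136).

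Between day 1 and day 2, let-7/miR-98, which promote differentiation, had 0 of 11 higher and 3 lower (median -0.85, camera adjusted p = 0.0466; adjusted p = 0.297 with an estimated correlation). let-7f-5p fell by 0.98 (SE 0.15, limma adjusted p = 0.00191). miR-106a-5p rose from 13.5 ± 19.1 to 139 ± 4.24 (log2 change 4.73, or 2.35 at the floor; SE 1.07, limma adjusted p = 0.0172). With it, 5 of 24 miR-17-92 miRNAs rose and 0 fell (8 and 0 adjusted over the list alone; median 0.49, camera adjusted p = 0.00404; adjusted p = 0.256 with an estimated correlation). Of Dlk1-Dio3, 14 of 84 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.49, camera adjusted p = 0.00868; adjusted p = 0.297 with an estimated correlation), miR-541-5p by 1.38 (SE 0.35, limma adjusted p = 0.0282). For miR-302/miR-367 the counts were 2 of 8 higher and 0 lower (median 1.78, or 1.34 at the floor; camera adjusted p = 0.0466, adjusted p = 0.256 with an estimated correlation). miR-3535 rose from 34.0 ± 19.8 to 196 ± 58.0 (2.59, SE 0.57, limma adjusted p = 0.0146), and miR-34c-5p went from 0 to 52.5 ± 9.19, which the common floor does not separate (adjusted p = 0.0866). miR-3473d, miR-341-5p and miR-7016-3p, at 395.5 ± 166.2, 315 ± 136 and 232 ± 1.41 on day 1, were listed at 0 in both day 2 libraries (-3.80, -3.46 and -3.09 at the floor; limma adjusted p = 4.24e-05, 4.07e-04 and 0.00126).

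In all, 33 miRNAs rose and 55 fell from day 1 to day 2 (limma, Benjamini-Hochberg adjusted p below 0.05), with 26 and 38 kept at the common floor. With libraries rescaled to the same total they were 17 and 60, and quantile normalization moved the median of all miRNAs from 0 to 0.16. The 88 calls were 53 without day 1 replicate 2, 57 without trend and robust options, 56 without entries numbered from 1900 and 34 in days 0 to 3 alone, where miR-34c-5p, miR-106a-5p and miR-3535 lost theirs (adjusted p = 0.102, 0.152 and 0.0835). Quantile normalization also ended the call of miR-3535 (0.0568). Leaving out single libraries also removed the calls of miR-34c-5p (adjusted p = 0.0556 without day 1 replicate 2 and 0.0573 without day 2 replicate 2), miR-106a-5p (0.0695 and 0.0676 without either day 2 library) and miR-3535 (0.0924 without day 1 replicate 1 and 0.0906 without day 2 replicate 2).

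From day 2 to day 3 miR-423-5p, encoded in Nsrp1 and among the most abundant miRNAs at the start, fell from 24666 ± 1330 to 8939.5 ± 362.7 (log2 change -1.46, SE 0.12, limma adjusted p = 1.11e-04). Both arms of the mirtron miR-877 fell, miR-877-3p from 371.5 ± 6.36 to 73.5 ± 4.95 (-2.32, SE 0.31, limma adjusted p = 0.00121) and miR-877-5p from 3259 ± 325 to 780.5 ± 389.6 (-2.15, SE 0.42, adjusted p = 0.0151). miR-16-5p, which slows the cell cycle, rose by 0.66 (SE 0.16, limma adjusted p = 0.0449). miR-100-5p, listed at 0 in both day 2 libraries, was at 885.5 ± 700.7 on day 3 (4.75 at the floor, limma adjusted p = 5.36e-05), and miR-5108 rose from 39.0 ± 1.41 to 249 ± 100.4 (2.58, SE 0.51, adjusted p = 0.0151). Of Dlk1-Dio3, 3 of 84 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.23, or 0.05 at the floor; camera adjusted p = 0.0123, adjusted p = 0.287 with an estimated correlation). Among them was miR-376b-3p, from 68.0 ± 7.07 to 203.5 ± 58.7 (1.54, SE 0.38, limma adjusted p = 0.0484).

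This step had the fewest calls, 17 higher and 16 lower (limma, Benjamini-Hochberg adjusted p below 0.05), with 8 and 14 kept at the common floor, 21 and 11 with libraries rescaled to the same total and 24 and 14 after quantile normalization. The 33 calls were 20 without day 2 replicate 2, 60 without day 3 replicate 2, 50 without ICM replicate 1, 19 without trend and robust options, 21 without entries numbered from 1900 and 6 in days 0 to 3 alone. The last setting ended the calls of miR-100-5p, miR-376b-3p and miR-877-5p (adjusted p = 0.0702, 0.35 and 0.0728), and array weights those of miR-376b-3p and miR-877-5p (0.0621 and 0.0568). With libraries rescaled to the same total the same 2 were lost (0.0588 and 0.0603). miR-376b-3p was also lost after quantile normalization (0.303), without trend and robust options (0.0812), without a filter (0.0938), with a pseudocount of 0.5 (0.0523), with a term for replicate number (0.0723), with 1 of each set of identical miRNAs (0.0506) and without entries numbered from 1900 (0.0698). Calls were lost without either day 2 library for miR-5108 (adjusted p = 0.052 and 0.0551), miR-877-5p (0.0553 and 0.0776; 0.123 without day 3 replicate 1) and miR-376b-3p (0.103 and 0.174; 0.242 without day 3 replicate 1, and 0.0531 to 0.0901 when a library of day 5 or ESCs was left out).

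Day 5 was compared with day 3 to follow the outgrowths up to the first passage. let-7/miR-98, whose loss goes with pluripotency, had 0 of 11 higher and 4 lower (median -0.61, camera adjusted p = 0.00473; adjusted p = 0.213 with an estimated correlation), and let-7e-5p fell by 0.95 (SE 0.18, limma adjusted p = 0.00282). miR-10b-5p fell by 3.21 (SE 0.47, limma adjusted p = 6.19e-04) and miR-351-5p by 1.56 (SE 0.29, adjusted p = 0.00282). miR-30a-3p rose from 24.5 ± 6.36 to 102.5 ± 3.54 (log2 change 2.04, SE 0.38, limma adjusted p = 0.00269) and miR-93-5p by 1.23 (SE 0.17, adjusted p = 3.35e-04). miR-302/miR-367 had 3 of 8 higher and 0 lower (median 1.37, camera adjusted p = 0.0485; adjusted p = 0.213 with an estimated correlation); at the common floor the median was 0.17 and the adjusted p 0.371.

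miR-3473d, listed at 0 in both day 3 libraries, was at 67.5 ± 33.2 on day 5 (1.22 at the floor, limma adjusted p = 0.0366), while miR-341-5p went from 0 to 23.5 ± 0.707, below the floor. miR-25-3p and miR-294-5p were listed at 0 in both day 5 libraries against 2412 ± 834 and 264 ± 12.7 on day 3 (-6.43 and -3.28 at the floor, limma adjusted p = 6.39e-09 and 0.0229). All other libraries hold miR-25-3p at 1716 to 14185. All others but day 1 replicate 2 hold miR-294-5p at 255 to 573. The source of these zeros is not known, so whether the cells lost either miRNA stays open. miR-100-5p fell from 885.5 ± 700.7 to 17.0 ± 8.49 (-5.44, or -4.75 at the floor; SE 1.3, adjusted p = 0.0137). The call of miR-294-5p was lost without day 3 replicate 1 or either day 5 library (adjusted p = 0.0595, 0.0653 and 0.0706), and that of miR-100-5p without day 3 replicate 1 (0.106) or day 5 replicate 1 (0.0954). Of 99 rises and 50 falls (limma, Benjamini-Hochberg adjusted p below 0.05), 32 and 42 were kept at the common floor. Quantile normalization gave 59 and 53, the median of all miRNAs moving from 0.58 to 0.09. The 149 calls were 96 without day 5 replicate 1 and 85 without day 5 replicate 2.

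**Figure D3:**
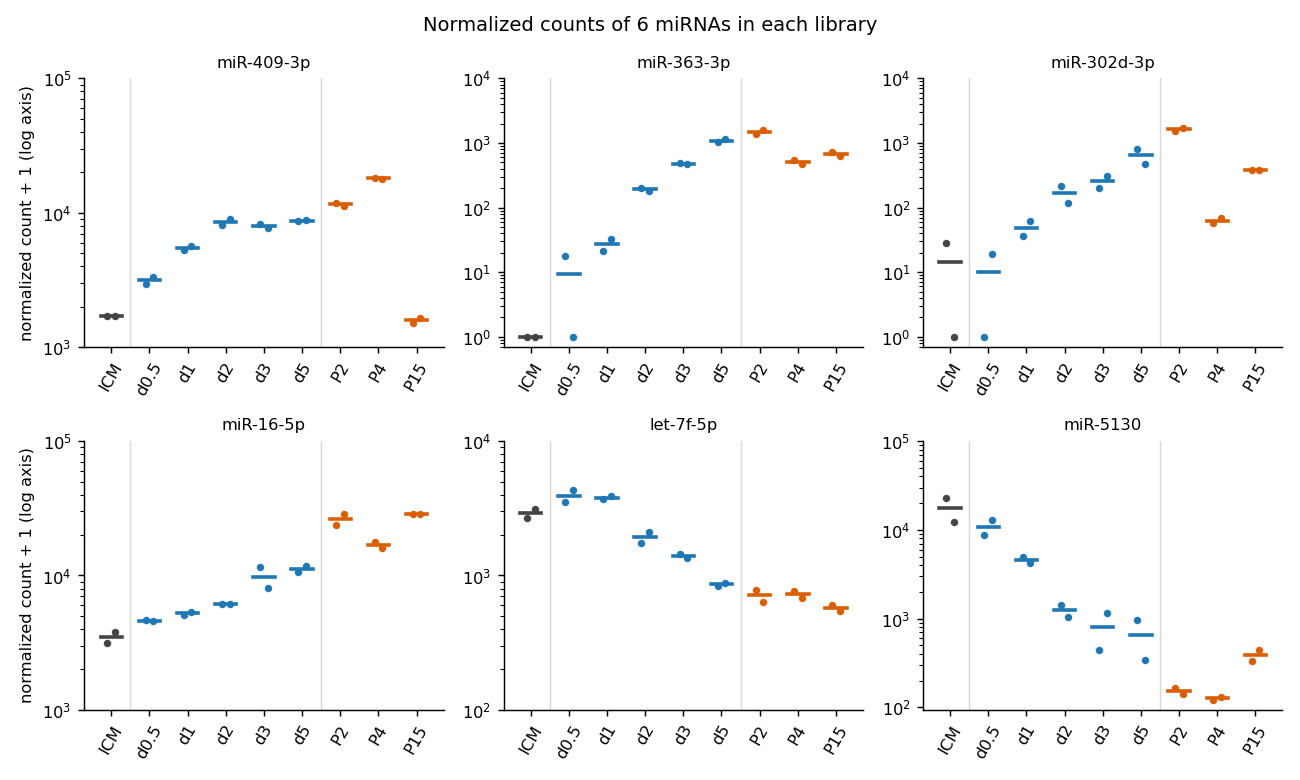
Normalized count plus 1 on a log axis for 6 miRNAs in each library. ICM (gray) and outgrowths (blue) are in order of time. ESC groups (orange) are placed by the code in the description, from which no order of passages is read.

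ESCs were compared with day 5 outgrowths to isolate the change from outgrowth to passaged line. The miR-290-295 cluster, specific to early embryos and ESCs, had 9 of 14 members higher and 0 lower (11 and 1 adjusted over the list alone; median 0.76, camera adjusted p = 2.79e-06; adjusted p = 0.144 with an estimated correlation). The rise of its most abundant member miR-292-5p (0.93, SE 0.11, limma adjusted p = 1.91e-04) was lost with libraries rescaled to the same total. miR-302/miR-367, of the primed epiblast, had 0 of 8 higher and 3 lower (0 and 4 adjusted over the list alone; median -1.18, camera adjusted p = 0.00958; adjusted p = 0.13 with an estimated correlation and 0.202 at the common floor). The fall came from P4 and P15, as its share was 0.25% on day 5, 0.48% in P2, 0.02% in P4 and 0.07% in P15. The X-linked miR-322/miR-503 cluster had 0 of 11 higher and 3 lower (median -0.97, camera adjusted p = 0.0203; adjusted p = 0.13 with an estimated correlation), miR-351-5p falling by 2.21 (SE 0.24, limma adjusted p = 1.07e-04). miR-126a-5p, the endothelial miRNA of Egfl7, rose from 152.5 ± 47.4 to 634 ± 299.6 (log2 change 1.95, SE 0.33, limma adjusted p = 0.00188).

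miR-25-3p and miR-294-5p, listed at 0 in both day 5 libraries, stood at 9711 ± 2958 and 454.5 ± 71.4 in ESCs (8.43 and 4.05 at the common floor, limma adjusted p = 3.66e-11 and 0.00123). Both were abundant before day 5 as well, and the source of the zeros is not known, so these rises may not be changes in the cells. miR-7091-5p fell from 181 ± 1.41 to 48.2 ± 46.6 (-3.48, SE 0.22, limma adjusted p = 2.03e-06; -1.90 at the floor), with 0 in both P2 libraries. miR-5119, at 36.0 ± 5.66 on day 5, and miR-5108, at 16.5 ± 3.54, were at 1 and 0 in ESCs, which the floor does not separate (adjusted p = 0.542 for miR-5119). In Dlk1-Dio3, 1 of 84 rose and 7 fell over all ESCs (median -0.13), but 18 rose and 1 fell (median 1.05) when P15 was left out. In all 48 miRNAs rose and 73 fell (limma, Benjamini-Hochberg adjusted p below 0.05), 43 and 58 kept at the floor. The floor fit itself called more, 103 higher and 87 lower, which turns the balance, and array weights called 208. With libraries rescaled to the same total the split was 21 and 96 and the median of all miRNAs moved from -0.05 to -0.41.

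The 3 ESC groups were compared with one another, without reading an order into them. miR-409-3p, of the maternally expressed Dlk1-Dio3 cluster, was at 11540 ± 538 in P2, 18004 ± 425 in P4 and 1578.5 ± 91.2 in P15 (SD, n = 2 each; limma F test, adjusted p = 7.96e-10). miR-540-3p of the same cluster was at 2438.5 ± 299.1, 12893 ± 253 and 571 ± 36.8 (adjusted p = 4.29e-09). miR-465a-3p and miR-465c-5p, of an X-linked cluster expressed in germ cells, were at 667.5 ± 67.2, 5193.5 ± 256.7 and 143 ± 19.8 (limma adjusted p = 1.60e-09) and at 1070.5 ± 82.7, 2816.5 ± 202.9 and 108.5 ± 13.4 (adjusted p = 5.75e-09). miR-7091-5p, in an intron of Dnase1l1 on X, ran the other way with 0, 42.0 ± 15.6 and 102.5 ± 0.707 (limma adjusted p = 9.93e-09). P15 differed from P2 and P4 by -3.19 log2 for miR-409-3p, -3.29 for miR-540-3p, -3.70 for miR-465a-3p, -3.99 for miR-465c-5p and 4.00 for miR-7091-5p, in contrasts added after seeing the data. The last value rests on the 0 of P2 and was 1.63 at the common floor (limma adjusted p = 8.34e-05).

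By list, 0 of 84 Dlk1-Dio3 miRNAs rose and 53 fell in P15 against P2 and P4 (0 and 74 adjusted over the list alone; median -3.38, camera adjusted p = 5.45e-42; adjusted p = 1.25e-04 with an estimated correlation). The median was -3.71, -3.27 and -2.86 under rescaling to the same total, quantile normalization and the common floor. Between P4 and P2 the miR-302/miR-367 cluster of the primed epiblast was lower in P4, 0 of 8 higher and 6 lower (0 and 7 adjusted over the list alone; median -4.42, or -2.87 at the floor; camera adjusted p = 3.86e-08, adjusted p = 0.0036 with an estimated correlation). miR-302b-3p fell from 534 to 21.5 (log2 change -4.57, SE 0.44, limma adjusted p = 2.45e-05). The Sfmbt2 cluster had 0 of 52 higher and 20 lower in P4 (0 and 23 adjusted over the list alone, with a median of -1.67, or -1.14 at the floor). The camera adjusted p was 3.30e-13, and 0.0357 with an estimated correlation. Some of the 52 share identical values, such as miR-466b-3p and miR-466c-3p, and count more than once in these results.

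Any difference among the 3 ESC groups was called for 222 miRNAs (limma F test, Benjamini-Hochberg adjusted p below 0.05), and for 492 with array weights. P15 had 74 higher and 85 lower than P2 and P4 (40 and 93 with libraries rescaled to the same total), and P4 had 72 higher and 72 lower than P2 (49 and 94). Pair by pair, calls numbered 173 for P15 and P2, 144 for P4 and P2, and 134 for P15 and P4.

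**Figure D4:**
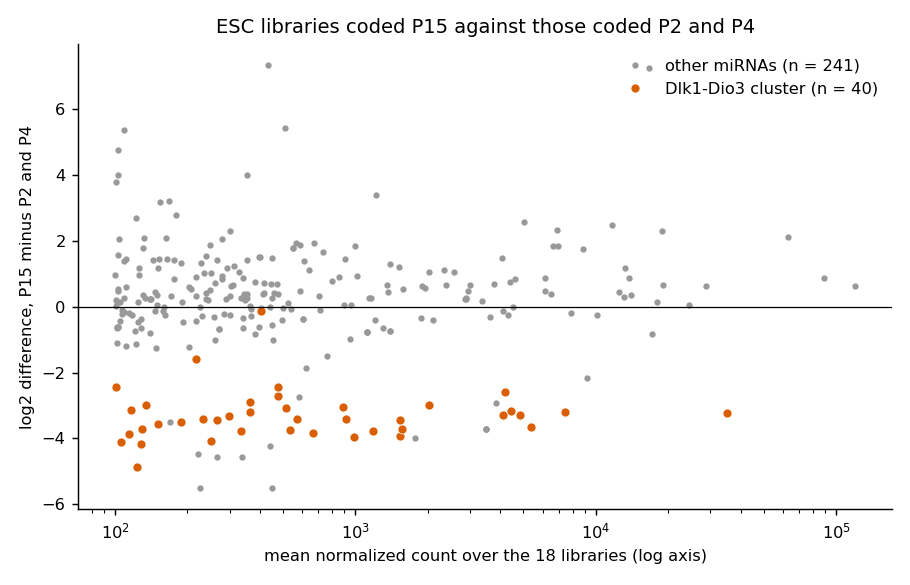
log2 difference between P15 and the mean of P2 and P4 against mean normalized count on a log axis, for 40 Dlk1-Dio3 miRNAs (orange) and 241 others (gray) with a mean of at least 100.

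All 9 groups were tested together for any difference. miR-423-5p stood at 23306 in ICM, 27327 on day 1 and 24666 on day 2, then at 2844 on day 5, 518 in P2, 2438.5 in P4 and 1389.5 in P15 (limma F test, adjusted p = 8.59e-11). miR-679-5p of the Dlk1-Dio3 cluster rose from 33.5 in ICM to 243.5 on day 1, 845 on day 5 and 2689.5 in P4, with 112.5 in P15 (adjusted p = 1.44e-09). miR-409-3p rose from 1705.5 in ICM to 8722.5 on day 5 (limma adjusted p = 9.61e-10), and miR-465a-3p went from 6578.5 on day 1 to 1210.5 on day 5 (adjusted p = 1.44e-09). miR-25-3p, listed at 0 on day 5, had the same adjusted p as miR-423-5p, 8.59e-11. A difference was called for 539 of 811 miRNAs (limma, Benjamini-Hochberg adjusted p below 0.05), for 488 at the common floor and for 351 without entries numbered from 1900.

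The balance of the 5p and 3p arms of 193 hairpins was compared between ESCs and ICM, because arms of a hairpin can be kept at different rates. The miR-290a hairpin, of the cluster linked to the ESC cell cycle, moved toward its 3p arm. miR-290a-5p was at 544 ± 38.2 in ICM and 282 ± 319.5 in ESCs, and miR-290a-3p went from 134 to 1036.5 ± 508 (log2 ratio change -7.35, SE 1.76, limma adjusted p = 0.00706; -4.97 at the common floor, adjusted p = 5.13e-04). miR-290a-5p is listed at 0 in 3 ESC libraries though abundant in the others, and these zeros make most of the change. In the other 3 it was at 564 ± 128.7, close to ICM, and the ratio changed by -2.20, which was not tested. The trophoblast-expressed miR-466c and miR-466b moved toward 5p (3.37 and 3.26 at the floor, limma adjusted p = 1.33e-08 and 2.74e-08). Their 5p arms were listed at 0 in both ICM libraries and reached 42.2 ± 31.9 and 38.7 ± 28.1 in ESCs, near the floor. Both were measured against the same 3p values, whose fall from 2227 ± 73.5 to 372.5 ± 221.2 makes most of the change at the floor. miR-182 moved toward 5p by 5.34 at the floor (limma adjusted p = 9.67e-05) and miR-423 toward 3p by 1.32 (adjusted p = 1.26e-05), 2 hairpins named after their values were seen. miR-450b toward 5p, and miR-212 and miR-222 toward 3p, also rested on arms listed at 0 in ICM (miR-222-3p, for instance, at 107 ± 60.3 in ESCs). Calls numbered 66, with 40 toward 5p and 26 toward 3p, and 38 of them were kept among the 129 hairpins that could be tested at the common floor. The floor fit itself called more, 84 hairpins, with 50 toward 5p and 34 toward 3p.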

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

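The predictions for the tests in this part were written after the results they concern had been seen. Exchange of single library labels, whose design was fixed beforehand, does not settle whether chance can be excluded as the source of the 420 calls between ESCs and outgrowths. Of 100 splits, 1 called as many, namely the real split itself, and the highest other split called 86 (140 against 378 at the common floor). These splits separate replicates, which by itself lowers the calls. Of 56 splits that keep replicates together, 2 called as many: the real one and that of days 0.5, 1 and 2 against the other groups, with 445 (387 at the floor), and the median of the others was 237. The count therefore does not set the step to ESCs apart from the course of derivation as a whole, or from depth, which moves with it.

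Rises from shallow to deep libraries were weighed against the lower depth of the day 0 to 3 libraries. If the 5-read minimum of the ICM libraries caused all rises in ESCs against ICM, few would be called once each library is held to the same lowest value, yet 76.2% were. Between day 3 and day 5 the picture differs, since 32.3% of rises and 84% of falls were kept, which is consistent with lower depth on day 3 as the cause of most of those rises. Which of the rises lost at the floor are changes in the cells stays open, as depth and stage coincide in these libraries.

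The 3 ESC groups differed from one another in 222 miRNAs (492 with array weights), with 134 to 173 calls in each pair of groups. In P15 the Dlk1-Dio3 miRNAs with a mean of at least 100 had a median of -3.40 log2, with 40 of 40 below 0, from -4.87 to -0.13 (miR-337-3p). Scaling of the P15 libraries does not account for it, since the cluster lies -3.75 log2 from the median of 241 other miRNAs. The library difference that parts replicates on day 3, day 5 and in P4 is not the whole of it either. There the lowest median of the cluster was -0.15, the SD of its members at most 1.25, and 18 to 26 of 40 lay below 0. By rank, the order of the members in P15 does follow those replicate differences (rho 0.506 to 0.611). Pearson r was 0.283 for day 3, -0.2 for day 5 and 0.254 for P4. Replicates were subtracted as 1 minus 2 on day 3 and in P4, and as 2 minus 1 on day 5. The P4 difference was set against P15 minus P2, the others against P15 minus P2 and P4. Whether the library difference adds to the falls of single members stays open. A mix-up of samples was not tested and stays open, all the more because titles and descriptions give the P15 libraries different passages. A change in the imprinting of the maternally expressed locus during culture, known from other mouse ESC lines, may be the cause, a hypothesis that methylation of the locus would test.

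Single miRNAs differed between the same groups by a tested contrast of P15 with P2 and P4: miR-409-3p by -3.19, miR-540-3p by -3.29, miR-465a-3p by -3.70, miR-465c-5p by -3.99 and miR-7091-5p by 4.00 log2, the last 1.63 at the common floor because P2 is listed at 0.

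Entries numbered from 1900 held their highest share on day 0.5. Few reads alone do not account for the gap to days 2 and 3, since the deeper day 0.5 library held 23.61% against 7.92% at most in 3 day 2 and day 3 libraries with fewer reads, 15.7 percentage points apart. Against day 0, whose libraries hold fewer reads and up to 18.85%, the gap was 4.8 points, less than the 7.9 between the day 0.5 libraries, of which the shallower held 31.49%. Whether few reads add to the rise from day 0 to day 0.5 therefore stays open. The rise from day 0 rests on a few abundant entries: without the 5 most abundant (miR-5099, miR-5126, miR-3968, miR-3963 and miR-2137) the day 0.5 share was 0.68 times the day 0 share, 7.21% against 10.61%. These entries were ranked on the same libraries, day 0.5 included, so the lower share is partly built in. The ratio therefore does not set this explanation above others. The remaining share on days 0 and 0.5 still lay above the highest late library, at 2.16%. Fragments of other small RNAs might be counted under some of these names, a possibility not tested here.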

How the results depend on the processing

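The common floor, the omission of entries numbered from 1900, days 0 to 3 alone, and the other added settings were chosen after seeing the data. None of the 76 named results changed direction under any setting that tested it, whereas list medians near 0 and miR-92a-3p did. The naming rule required all libraries or group means of one side above those of the other. Most settings could therefore hardly reverse a named result, while list medians were not chosen in that way. Of the 76, 47 were kept under every setting that tested them, but some settings tested fewer. Leaving out abundant miRNAs listed at 0 tested 69, leaving out entries numbered from 1900 tested 50, and leaving out P15 tested 36. Results for miRNAs left out of a setting could not be lost there, so the 47 can include results that rest on such zeros. Array weights removed 15 calls, days 0 to 3 alone 13 of 24, the common floor 8 and rescaling to the same total 3. Quantile normalization removed 2 and single left-out libraries 0 to 6.

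With a mean of at least 100 required, fewer miRNAs were tested and the counts were 230 for ESC against ICM, 181 for outgrowths against ICM, 218 for ESC against outgrowths, 35 for day 1, 69 for day 5, 267 over all groups and 21 for arms. Array weights gave 250 for ESC against ICM, 61 for outgrowths against ICM, 20 for day 0.5, 57 for day 1, 208 for ESC against day 5 and 492 among ESC groups; the cause was not tested. Without trend and robust options day 2 had 57 and day 3 had 19 (cause not tested). At the common floor ESC against day 5 had 190 calls, 103 higher and 87 lower (cause not tested). Without entries numbered from 1900, 527 miRNAs were tested, with 269 calls for ESC against outgrowths, 39 for day 0.5, 36 for day 1, 56 for day 2, 21 for day 3 and 351 over all groups. Days 0 to 3 alone, with fewer samples, gave 58, 57, 34 and 6 for days 0.5, 1, 2 and 3. Estimated correlation left 1 list called, and fry called 17 (cause not tested). The exact test of shares over whole groups, added after seeing the data, called 0 lists, an outcome nearly fixed by its 56 splits.

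With 1 library left out, a group's lone sample is assumed to vary like the other groups. The ranges were 404 to 501 for ESC against ICM, 251 to 328 for outgrowths against ICM, 359 to 483 for ESC against outgrowths, 64 to 168 for day 0.5, 63 to 160 for day 1, 53 to 114 for day 2, 20 to 60 for day 3, 85 to 173 for day 5, 81 to 142 for ESC against day 5, 163 to 265 among ESC groups, 458 to 569 over all groups, 3 to 4 for lists, 56 to 70 for arms and 10 to 14 for shares.

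Replicate numbers showed no steady pairing of libraries across groups. The 36 pairs of replicate differences correlated from -0.448 to 0.381, with 6 above 0.1 and 12 below -0.1. A term for replicate number left the counts near the deposited ones (444 for ESC against ICM, 528 over all groups, 3 lists, 61 arms). Such a term cannot absorb a library difference that runs with opposite numbers, as between day 3 and day 5 (r = -0.397), so a shared difference of that kind stays open. Negative binomial count models, fixed as alternatives beforehand, were not run, because whole reads cannot be recovered from the rounded values of 8 libraries. Depth limits the day 0 to 3 libraries: a miRNA below 5 reads there cannot be told from 0.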

Other observations

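The genomic window for the cluster in this part was chosen after its values were seen. Beside miR-465, further miRNAs of the same X-chromosome cluster, which lies near Fmr1 and is known from testis, were low in P15. Of 22 tested miRNAs between X:66777256 and X:66835842, miR-465 included, 11 fell and 0 rose in P15 against P2 and P4 (median log2 change -3.52, or -3.63 with libraries rescaled to the same total and -3.09 after quantile normalization). The 11 include miR-465c-5p and miR-465b-3p, whose values, the latter identical to those of miR-465a-3p, had led to the window. At the common floor the median was -2.76, taken only over those of the 22 that were high enough to be tested there. miR-743b-3p changed by -5.51 (SE 0.25, limma adjusted p = 2.15e-08), miR-741-3p by -4.57 (SE 0.47, adjusted p = 2.11e-05), miR-878-5p by -4.56 (SE 0.32, adjusted p = 1.16e-06) and miR-871-5p by -4.22 (SE 0.17, adjusted p = 3.88e-09). At the floor these changes were -3.23, -3.48, -3.10 and -4.00. Between P4 and P2, 5 rose and 0 fell (median 0.99), and miR-470-5p was at 1778 ± 86.3 in P2, 20616.5 ± 12680 in P4 and 1277.5 ± 112 in P15 (P4 minus P2 3.38, SE 0.47, limma adjusted p = 3.33e-04).

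Along derivation the cluster's share of all normalized counts was 4.13 ± 0.52% in ICM, 4.17% on day 1, 3.01% on day 2 and 1.28% on day 5, then 0.77% in P2, 3.5 ± 0.96% in P4 and 0.16% in P15. miR-465b-3p, listed with the same values as miR-465a-3p, was lower in ESCs than in ICM by 2.16 on average (SE 0.12, limma adjusted p = 6.07e-08), but P4 lay above ICM, at 5193.5 ± 257 against 3551 ± 416.

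In some libraries 7 miRNAs were listed at 0 that were abundant in the others. miR-25-3p was at 0 in both day 5 libraries, miR-92b-3p in ICM replicate 1 and both P2 libraries, miR-148b-3p in both P2 libraries and P4 replicate 1 (237 to 813 elsewhere), and miR-294-5p in day 1 replicate 2 and both day 5 libraries (255 to 573 elsewhere). miR-26b-5p was at 0 in day 5 replicate 1 and both P4 libraries, miR-290a-5p in P15 replicate 1 and both P2 libraries, and miR-181d-5p in ICM replicate 2. Identical values in all 18 libraries were listed for 8 sets of miRNAs with 18 members, such as miR-199a-3p with miR-199b-3p and miR-466a-3p with miR-466e-3p.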
